A study of Homo sapiens with 6 samples.

How the data were processed

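HUVECs, primary human endothelial cells of the umbilical vein, were plated and left overnight, then transfected by lipid reagent with a miR-409-3p mimic or a non-specific control RNA at 50 nM, and RNA was taken at 48 h, per the labels' protocols. Libraries were made from 500 ng of total RNA by mRNA enrichment, enzymatic fragmentation and 13 PCR cycles, and were sequenced as single 75-cycle reads, per the labels' protocols. The series' design text says that 4 technical replicates went into the pool behind each RNA sample. The labels number the replicates 1 to 3 in each group and call them biological replicates. Separate donors or cultures are not named, so p-values measure the spread between these samples, which may be technical. Groups were taken from the sample titles, and the treatment label gives the same groups. The titles of all 6 libraries, mimic and control, also call the cells not treated, and the labels do not say which treatment is meant.

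The authors deposited 1 table per library with a TPM value (read counts divided by gene length and scaled to the same total in each library) for each of 45372 Ensembl gene IDs, per the file headers. The builds hg38 and GRCh38.p13 are named in the submitters' processing notes. The aligner, the counting program, the gene annotation, the use of strand and any read filter are not given in the sources used here. Gene symbols came from a table of Ensembl IDs, in which 45102 of the 45372 IDs were found, and gene positions, types and transcript sequences from GENCODE release 29 on GRCh38, which held 43348 of them and 13601 of the 13680 genes tested.

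TPM keeps no depth of its own. For 3465 of 4128 low genes, 83.9%, the values of the 6 libraries were whole multiples of a single step within 0.02 steps, and for 2396 of the 3278 of these with a GENCODE 29 length the step matched 1 read over the exon length. The depth this implies was 32.2, 32.8 and 34.8 M assigned reads for control libraries 1 to 3, and 32.1, 35.8 and 29.8 M for mimic libraries 1 to 3. These are estimates from the values, and reads carried no molecular identifiers, so PCR copies are included.

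The main comparison was fitted with limma 3.58.1 in R 4.3.3 (trended prior variance, group as the only term) on log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, 13680 in all, and p-values were adjusted by Benjamini-Hochberg over them with a threshold of 0.05. Fold changes are mimic minus control on the log2(TPM + 1) scale, which understates the change of low genes. Named genes were BTG2, the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, at least 5 TPM in the higher group and no overlap between the groups' values, up to 3 genes past the threshold from each list, and all that passed among the reported miR-409-3p targets. Some other genes are named in the text beyond this rule, and those were chosen after their values were seen.

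The 30 gene lists were tested two-sided with camera of limma at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 28 lists with at least 3 tested genes, and again with an estimated correlation and with fry. They cover reported miR-409-3p targets, the BTG/TOB family with the CCR4-NOT complex, the mTOR pathway, angiogenic ligands and receptors, tip cell genes, the Notch pathway, endothelial identity, S phase, G2/M, p53 targets, the interferon response, NF-kB genes, endothelial-to-mesenchymal genes, basement membrane and integrins, migration and actin, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and ATF4 response, shear-responsive genes, immediate early genes, the microRNA machinery, markers of smooth muscle, fibroblasts, leukocytes, epithelium, blood and platelets, and lymphatic endothelium, mitochondrial transcripts, replication-dependent histones, and ribosomal proteins.

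Seed sites were searched in the longest annotated 3′ UTR (at least 30 nt) of each tested protein-coding gene, 11836 genes. The seed, bases 2 to 8 of the mature miR-409-3p (GAATGTTGCTCGGTGAACCCCT as DNA), pairs with CAACATT. Classes were 8mer (CAACATTA), 7mer-m8 (CAACATT), 7mer-A1 (AACATTA), 6mer (AACATT) and none. Medians were compared with a two-sided permutation test over genes (100000 resamples, smallest possible p 1e-05) and 1000 bootstrap draws for 95% intervals. Genes are not independent replicates, so this test covers the spread between genes and not between libraries. Each 7-mer was also ranked by a rank-sum z of fold changes after regression on log2 UTR length and UTR GC. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

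The comparison was tested on simulated data of the same 13680 genes with 200 changed, in 20 runs. limma recovered 18.1% of 1.25-fold, 58.1% of 1.5-fold and 78.3% of 2-fold changes, and 4.73% of calls were false. camera recovered a list of 30 genes raised by 0.2 in 20 of 20 runs and called an unchanged list in 0 of 20. In 10 simulated sets of 11836 fold changes with sites lowered by 0.1, CAACATT ranked first among all 7-mers in 10 of 10. Smaller lowerings were not simulated, so this rank does not tell whether a smaller one could be seen. All simulated noise was drawn independently for each gene. The rates of recovery and of false calls and the simulated rank therefore do not cover genes that vary together. In the data the z of 7-mers ran from -5.06 to 5.15.

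Alternatives set before the data were examined were a replicate block, leaving out each library, pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios and quantile scaling, an untrended prior, other thresholds, an estimated correlation, fry, other site classes, UTR covariates and the canonical transcript. The robust prior, the restriction to protein-coding genes and the APPRIS principal transcript were chosen after seeing the data. XIST and Y-linked genes are not reported.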

Results

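RNA-seq was collected from human umbilical vein endothelial cells, primary cells widely used to study vessel growth, 48 h after transfection with 50 nM of a synthetic miR-409-3p mimic (3 libraries) or of a non-specific control RNA (3 libraries). The series title ties miR-409-3p and BTG2 to angiogenesis and wound healing in obese mice, and this experiment asks which endothelial transcripts differ when the microRNA is supplied. The estimated depth was 29.8 to 35.8 M assigned reads per library. Mitochondrially encoded transcripts took 8.65% to 9.99% of TPM. Libraries of the same group correlated across genes at a Pearson r of 0.988 to 0.992 and libraries of different groups at 0.988 to 0.991, so this correlation did not set the groups apart. Principal component 1 held 26.7% of the variance, with mimic libraries at 7.58, 22.3 and -8.19 and control libraries at -6.27, -10.6 and -4.85, so the groups overlapped on it. Principal component 2 held 24.2%, with mimic libraries at -8.30, 2.55 and -19.2 and control libraries at 6.10, 3.73 and 15.1. On component 2 every mimic library lay below every control library.

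BTG2, an antiproliferative gene of the BTG/TOB family and a p53 target, was lower in every mimic library than in every control library. It measured 80.0 ± 1.05 TPM in control cells and 51.6 ± 5.22 TPM in mimic cells (mean ± SD, n = 3 each), 0.646 of the control level. The log2 fold change was -0.63 with a standard error of 0.08, and BTG2 fell by the limma test (Benjamini-Hochberg adjusted p = 0.0143). BTG2 (ENSG00000159388) lies on the plus strand of chromosome 1 at 203305491 to 203309602 in GRCh38. Its annotated 3′ UTR of 2164 nt held no match to the miR-409-3p seed, with 0 copies of the 6mer AACATT, and its coding sequence also held 0. The limma adjusted p exceeded 0.05 when some libraries were left out, at 0.0823 (fold change -0.62), 0.0699 (-0.64) and 0.0785 (-0.63) without control library 1, 2 and 3 and at 0.0582 (-0.66) without mimic library 1. It was 0.120 with no filter on low genes and 0.0550 with an untrended prior.

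**Figure D1:**
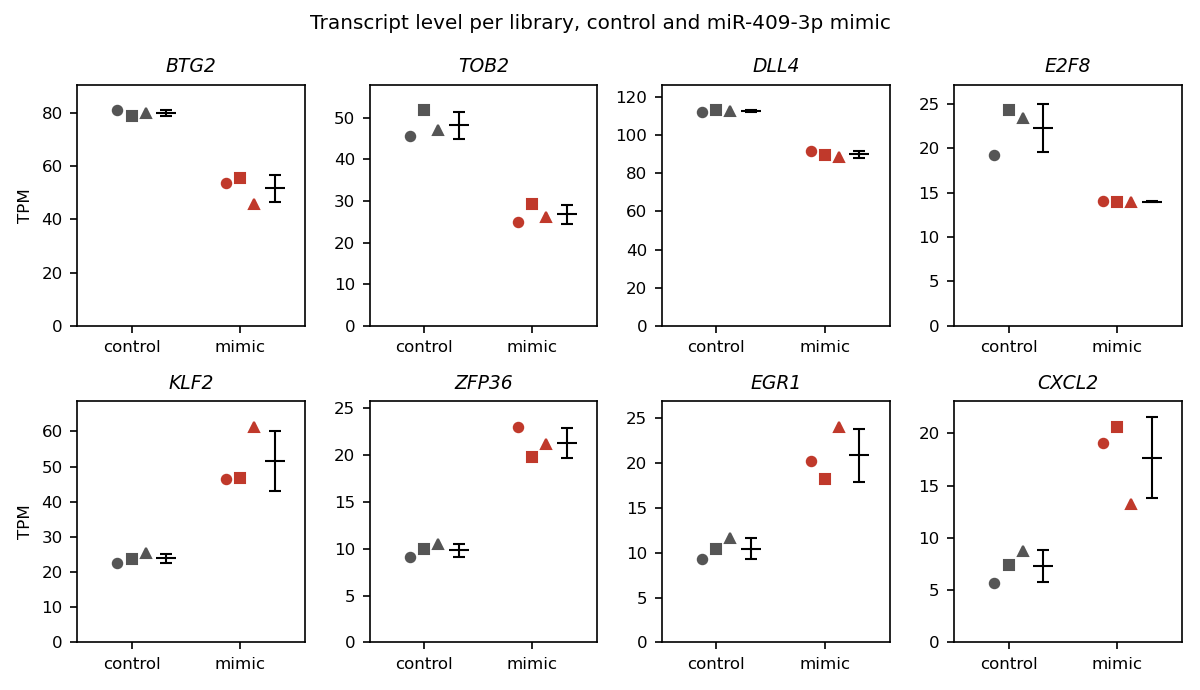
TPM (vertical axis, from 0) of 8 named genes in each control library (grey) and each mimic library (red), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of n = 3. BTG2, TOB2, DLL4 and E2F8 are lower and KLF2, ZFP36, EGR1 and CXCL2 higher in all 3 mimic libraries.

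Across the transcriptome mimic and control cells differed in 59 of 13680 genes. KLF2, a flow-responsive endothelial transcription factor, rose from 23.9 ± 1.35 to 51.5 ± 8.48 TPM, 2.16 times the control level. ZFP36, which encodes an mRNA decay factor, rose from 9.82 ± 0.704 to 21.3 ± 1.62 TPM, and EGR1 rose from 10.4 ± 1.16 to 20.8 ± 2.93 TPM. The chemokine gene CXCL2 rose from 7.28 ± 1.53 to 17.6 ± 3.87 TPM, and TXNIP, a thioredoxin-binding protein gene, rose from 31.5 ± 4.62 to 62.7 ± 7.47 TPM (mean ± SD, n = 3 for each value).

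By limma with Benjamini-Hochberg adjustment, 18 genes rose and 41 fell among 13680 tested, and 1462 genes had an unadjusted p under 0.05, of which 417 were higher and 1045 lower. A split of the libraries that mixed the groups gave 1564 genes at that unadjusted p. All 59 had no overlap between the groups, as had 15.7% of tested genes, against 10% by chance. The other large rises under the naming rule were NFKBIZ (log2 fold change 0.95, SE 0.12), SPRY4 (0.76, SE 0.10), SNRK (0.64, SE 0.06) and MYLIP (0.62, SE 0.07). RN7SL4P, a short pseudogene of the 7SL RNA, was listed at 0 in all control libraries and at 3.75, 5.34 and 9.88 TPM in mimic libraries, an estimated 45 reads in total, and near-identical 7SL copies can share such reads. Among genes with a symbol, at least 5 TPM in the higher group and no overlap between groups, the largest falls were ZSWIM3 (-0.84, SE 0.13), TOB2 (-0.83, SE 0.08), HSPA1B (-0.80, SE 0.10), ZNF366 (-0.72, SE 0.07), USPL1 (-0.71, SE 0.06), ZNF786 (-0.70, SE 0.10), PPP1R10 (-0.68, SE 0.06), PCF11 (-0.63, SE 0.06), ZNF616 (-0.63, SE 0.09) and E2F8 (-0.63, SE 0.09). Outside that rule and chosen after the values were seen, ENSG00000268465, a gene without a symbol that overlaps annotated genes on both strands, was listed at 5.45, 4.71 and 8.86 TPM in control libraries and at 0, 0 and 0.897 TPM in mimic libraries (log2 fold change -2.53, SE 0.29), and CLK4 fell from 4.98 ± 0.536 to 2.70 ± 0.113 TPM (n = 3). HSPA1B may share reads with its near-identical copy HSPA1A, and how such reads were counted is not given. PCF11, E2F8 and SNRK overlap annotated antisense genes, and PCF11, ZNF616 and HSPA1B overlap another annotated gene on their own strand, so reads of these genes may be shared and their values are uncertain. The adjusted p of the 20 genes ranged from 0.00507 for ZFP36 to 0.0440 for ZSWIM3. Median-of-ratios scaling gave 33 rises and 54 falls and quantile scaling 34 and 42, against 18 and 41. The counts were 6 and 5 with no filter, 36 and 79 with a filter of 5 TPM, 10 and 10 with an untrended prior, 37 and 82 with a robust prior and 54 and 121 with protein-coding genes only. Without control library 1, 2 or 3 the counts were 6 and 10, 8 and 6, and 11 and 7, and without mimic library 1, 2 or 3 they were 7 and 10, 19 and 27, and 22 and 24. Across 16 other settings, ZFP36 and SNRK passed in 16, KLF2 in 14, MYLIP in 12, EGR1 and SPRY4 in 11, TXNIP and NFKBIZ in 10 and CXCL2 in 7, and RN7SL4P in 12 of 14. Of the falls, USPL1 and PPP1R10 passed in 16, TOB2 and PCF11 in 15, ZNF366 in 13, HSPA1B in 10, ZNF786, ZNF616 and E2F8 in 8 and ZSWIM3 in 6. The fold change of ZSWIM3 ran from -1.02 to -0.47 over these settings.

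Of the lists, the immediate early genes, transcripts induced within minutes by growth and stress signals, had the lowest camera p (adjusted p = 1.34e-06, and adjusted p = 0.871 with an estimated correlation). Of its 28 tested members, 3 rose (ZFP36, EGR1 and SPRY4), 0 fell and 25 did not pass, and the median log2 fold change was 0.09. At an unadjusted p under 0.05, 12 were higher and 1 lower, and adjusted over the list alone 10 rose and 1 fell. Below the threshold over all genes, JUNB had a log2 fold change of 0.38 (SE 0.08), HBEGF 0.44 (SE 0.08) and IER3 -0.18 (SE 0.04). The NF-kB inflammatory and adhesion list had 28 tested genes, of which NFKBIZ and CXCL2 rose, 0 fell and 26 did not pass, with 8 higher and 1 lower at an unadjusted p under 0.05 and 7 rises adjusted over the list alone. NFKBIA, the feedback inhibitor of NF-kB, had a log2 fold change of 0.43 (SE 0.07), the adhesion genes ICAM1 and SELE had 0.23 (SE 0.22) and 0.25 (SE 0.23), and CSF3, a colony-stimulating factor gene, had -0.45 (SE 0.16).

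In the endothelial identity list KLF2 rose and 38 of 39 genes did not pass, with 2 higher and 1 lower adjusted over the list alone and a median of 0.05. KLF2 was also the 1 riser among 26 shear-responsive and nitric oxide genes, where 25 did not pass and 2 rose adjusted over the list alone. By camera with Benjamini-Hochberg adjustment the immediate early (adjusted p = 1.34e-06), NF-kB (8.69e-04) and endothelial identity (0.0102) lists were higher, and the shear list did not pass (0.0928). With an estimated correlation the adjusted p was 0.871 for each of these lists, and fry gave 0 lists in a single direction. For change in either direction, which fry tests apart, 10 lists passed, among them immediate early (adjusted p = 7.83e-04), NF-kB (0.0173), endothelial identity (0.0024) and p53 target genes (4.98e-04). The rest were Notch (1.28e-04, the lowest), tip cell (4.98e-04), shear (4.98e-04), BTG/TOB (7.83e-04), unfolded protein (0.0029) and reported target genes (0.0184), which did not pass camera. At an unadjusted p under 0.05 camera gave 8 lists, 0 with an estimated correlation, and fry 2. The NF-kB median of 0.06 turned to -0.0047 without control library 1 and to -0.0073 with a filter of 5 TPM. Quantile scaling ended the endothelial identity call at an adjusted p of 0.168.

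Of 32 tested p53 targets, BTG2 fell, 31 did not pass, and 23 had a fold change below 0, with a median of -0.06. Adjusted over the list alone 9 fell and 0 rose. Members below the threshold over all genes included SESN2 at -0.56 (SE 0.11), PLK3 at -0.49 (SE 0.11) and BBC3 at -0.35 (SE 0.09), while CDKN1A measured 184 ± 18.7 TPM in control and 159 ± 18.0 TPM in mimic cells (n = 3). GADD45A, a stress gene that the list did not hold, went the other way. It rose from 194 ± 0.442 to 275 ± 8.18 TPM (limma with Benjamini-Hochberg, adjusted p = 0.00618). The list result therefore covers its own members only and depends on which genes were put on it. The list passed camera with Benjamini-Hochberg adjustment (adjusted p = 0.0102) and had an adjusted p of 0.871 with an estimated correlation.

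**Figure D2:**
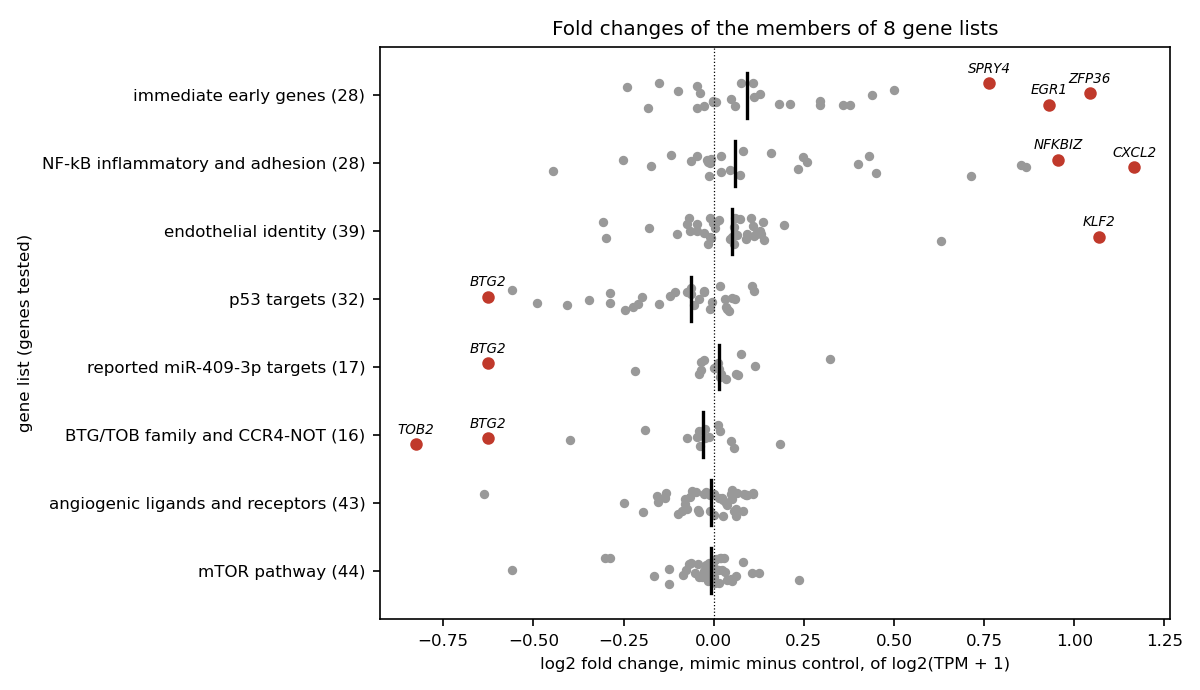
Log2 fold change of log2(TPM + 1), mimic minus control (horizontal axis), of the tested members of 8 gene lists, with red labelled points for genes past the limma threshold, grey points for the rest and a black bar at each list's median. The immediate early, NF-kB and endothelial identity medians lie at 0.09, 0.06 and 0.05 and the p53 target median at -0.06, and under a filter of 5 TPM the NF-kB median is -0.0073.

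Among the BTG/TOB family and the CCR4-NOT deadenylase it contacts, TOB2 fell from 48.2 ± 3.18 to 26.7 ± 2.25 TPM along with BTG2, and 14 of 16 members did not pass, with 3 falls adjusted over the list alone. TOB1 had a log2 fold change of -0.40 (SE 0.12) and BTG1 of 0.18 (SE 0.08). DLL4, the Notch ligand of sprouting tip cells, fell from 112 ± 0.464 to 89.9 ± 1.71 TPM (log2 fold change -0.32, SE 0.05, limma with Benjamini-Hochberg, adjusted p = 0.0321), and it passed in 7 of 16 other settings. DLL4 was the 1 gene to pass among 16 Notch pathway and 23 tip cell genes, with 1 and 2 falls adjusted over each list alone. HEY1 was at -0.36 (SE 0.10) and CXCR4 at -0.25 (SE 0.06). The camera adjusted p was 0.216 for BTG/TOB, 0.734 for Notch and 0.692 for tip cells. For change in either direction the fry adjusted p was 7.83e-04, 1.28e-04 and 4.98e-04, which does not tell how many members changed.

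Angiogenic ligands and receptors gave 0 genes past the threshold among 43, with 1 fall adjusted over the list alone, and the mTOR pathway gave 0 among 44, again with 1 fall, by limma with Benjamini-Hochberg. At an unadjusted p under 0.05, 0 angiogenic genes were higher and 4 lower, and 1 mTOR gene was higher and 4 lower. KDR, the main VEGF receptor, measured 349 ± 18.3 TPM in control and 377 ± 14.6 TPM in mimic cells, and ANGPTL4 10.7 ± 0.850 and 6.58 ± 1.31 TPM (n = 3). E2F8 was the 1 of 40 S phase genes to fall, also over the list alone, and 0 of 39 G2/M genes passed, with 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 2 genes rose in the unfolded protein and ATF4 list, 1 fell among the endothelial-to-mesenchymal genes and 1 fell in the microRNA machinery. No gene passed limma, over all genes or over the list alone, among 34 interferon, 37 basement membrane and integrin, 41 migration and actin, 34 hypoxia and glycolysis, 27 cholesterol, 13 mitochondrial, 15 histone and 48 ribosomal protein genes. Over all genes, 0 of 35 unfolded protein and ATF4, 25 endothelial-to-mesenchymal and 26 microRNA machinery genes passed. At an unadjusted p under 0.05, higher and lower genes numbered 3 and 3 for interferon, 3 and 0 for basement membrane, 0 and 1 for migration, 1 and 1 for hypoxia, 0 and 2 for cholesterol, 0 and 0 for mitochondrial, 1 and 0 for histone and 0 and 0 for ribosomal genes, and 3 and 4 for unfolded protein, 2 and 1 for endothelial-to-mesenchymal and 0 and 3 for microRNA machinery genes. The camera adjusted p of these lists ranged from 0.0928 for basement membrane and microRNA machinery to 0.960 for mTOR. The median and the camera direction differed in sign for the mTOR, angiogenic, migration, epithelial and ribosomal lists, and the median and the mean for the reported targets, tip cell, and unfolded protein lists, and for the last 3 camera followed the median. The direction given by camera is relative to the other tested genes, and the median of all tested genes was -0.0166. The mTOR, angiogenic, migration and ribosomal medians lay above that value, and the epithelial median, at -0.0187, lay below it.

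Markers of other cell types did not separate the groups. Of these, 0 passed among 5 smooth muscle, 5 fibroblast, 2 leukocyte, 6 epithelial and 8 lymphatic entries tested, over all genes or the list alone, and 0 of 14 blood and platelet genes reached the filter. At an unadjusted p under 0.05, 1 lymphatic gene was higher, 1 was lower and 0 genes of the other marker lists passed. COL1A2 measured 8.03 ± 1.51 and 8.62 ± 0.920 TPM, and EPCAM 2.14 ± 0.461 and 2.09 ± 0.509 TPM, in control and mimic cells (n = 3). CLEC14A, an endothelial surface gene, measured 1112 ± 19.9 and 1224 ± 23.7 TPM.

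The last comparison concerned direct targeting, since a microRNA commonly lowers transcripts that pair with its seed. Of 17 tested genes reported as miR-409-3p targets, BTG2 fell, 0 rose and 16 did not pass, and adjusted over the list alone 1 rose, CITED2 (log2 fold change 0.32, SE 0.07), and 1 fell. The 5 targets with an 8mer site, CITED2 among them, measured 0.0010 (MAP4K3), 0.01 (GAB1), 0.04 (ZEB1), 0.12 (RDX) and 0.32 (CITED2) in log2 fold change. The 5 with a 7mer-m8 site measured -0.22 (DNAJB9, SE 0.08, limma adjusted p = 0.358), -0.04 (ELF2), -0.03 (ANG), 0.02 (AKT1) and 0.07 (CTNND1), and DNAJB9 and BTG2 were the 2 targets lower at an unadjusted p under 0.05. The camera adjusted p of this list was 0.674, and the fry adjusted p for change in either direction was 0.0184. Across the transcriptome, 1555 genes with CAACATT in the 3′ UTR had a median log2 fold change of -0.016 and 6486 genes with no 6mer had -0.021. The difference of 0.0046 (95% bootstrap interval -0.0013 to 0.012) had a two-sided permutation p of 0.127 over genes. The median was -0.011 for the 369 genes with an 8mer, -0.018 for 1186 with a 7mer-m8, -0.014 for 1122 with a 7mer-A1 and -0.016 for 2673 with a 6mer.

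Falling genes carried a 7mer or 8mer site in 9 of 39 cases (23.1%) and rising genes in 4 of 16, against 22.6% of 11836 searched genes, with two-sided Fisher's exact p of 1 and 0.769. From the lowest z, CAACATT ranked 12711 and AACATTA 15643 of 16383 7-mers, and GGTAACC, the site of the passenger strand, 3169. The difference depended on single libraries. It was -0.0075, -0.0021 and 0.024 without control library 1, 2 and 3, and 0.0079, -0.035 and 0.040 without mimic library 1, 2 and 3. The permutation p over genes was 1e-05, the smallest possible, without control library 3, mimic library 2 or mimic library 3, while the z of CAACATT, which is adjusted for UTR length and GC, stayed between 0.12 and 2.29 in these fits.

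**Figure D3:**
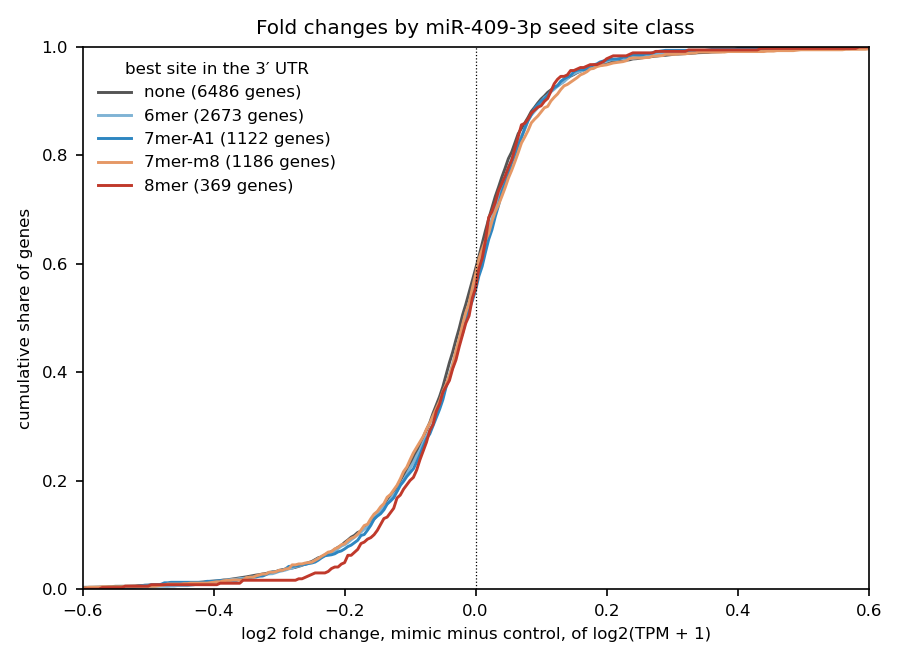
Cumulative share of genes (vertical axis) against the log2 fold change of log2(TPM + 1), mimic minus control (horizontal axis, shown from -0.6 to 0.6), for genes grouped by the best miR-409-3p site in the 3′ UTR. The 5 curves nearly coincide, with medians from -0.021 with no site to -0.011 with an 8mer.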

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

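The robust prior, the protein-coding restriction and the APPRIS transcript were chosen after the data were seen. The canonical transcript was not run, as the annotation carries no such tag. Higher and lower counts, 18 and 41, became 6 and 5 with no filter, 36 and 79 with 5 TPM, 10 and 10 with an untrended prior, 37 and 82 with a robust prior, 54 and 121 with protein-coding genes only, 58 and 134 at an adjusted p under 0.1, and 5 and 1 at a log2 fold change of at least 1. Higher counts were 33 with median-of-ratios and 34 with quantile scaling. Without 1 library, counts spanned 6 to 22 and 6 to 27, and no called gene changed sign. BTG2 stayed at -0.63 but missed 0.05 with no filter (adjusted p 0.120) and an untrended prior (0.0550), within a limma range of 0.0039 to 0.120, and measured -0.68 to -0.54 without 1 library. Replicate numbers did not pair the samples (correlations of deviations 0.03, -0.09 and -0.11, and 2 of 6 libraries correlated best with their own number). With them as a replicate block the counts were 9 and 5, BTG2 was at -0.63 (adjusted p 0.0569) and 4 lists passed. Of 21 other named genes, 4 kept the call in every setting (PPP1R10, SNRK, USPL1 and ZFP36). The 4 lists became 0 with an estimated correlation and 0 with the directional fry test, and 4 to 7 without 1 library, with 7 without control library 1 (adding microRNA machinery at a camera adjusted p of 0.0125, mitochondrial at 0.0038 and ribosomal genes at 4.55e-05), 5 without mimic library 3 (cholesterol, 0.0111), 5 with median-of-ratios (basement membrane, 0.0427), 5 with no filter (microRNA machinery, 0.0220) and 3 with quantile scaling. The seed difference of 0.0046 ranged from -0.035 to 0.040 without 1 library, and was 0.0074 with 7mer-A1 sites (permutation p over genes 0.0389) and 0.0099 with quantile scaling (8.80e-04), and the rank of CAACATT ran from 8557 to 14863. List medians changed sign as follows. Median-of-ratios gave 0.0135 for mTOR, 0.0135 for angiogenic, 0.0053 for S phase, 0.0097 for migration and 0.0050 for ribosomal genes. Quantile scaling gave 0.011 for mTOR, 0.0016 for migration and 0.0016 for epithelial genes. A filter of 5 TPM gave 0.0012 for angiogenic and -0.0073 for NF-kB genes, and no filter 0.0096 for epithelial genes. Without 1 library, medians spanned -0.035 to 0.032 for reported targets, -0.023 to 0.011 for mTOR, -0.024 to 0.024 for angiogenic, -0.024 to 0.042 for tip cell, -0.059 to 0.025 for Notch, -0.035 to 0.019 for S phase, -0.050 to 0.0017 for interferon, -0.0047 to 0.16 for NF-kB, -0.0058 to 0.053 for basement membrane, -0.039 to 0.023 for migration, -0.013 to 0.042 for hypoxia, -0.023 to 0.033 for ATF4, -0.041 to 0.079 for fibroblast, -0.090 to 0.031 for epithelial, -3.67e-04 to 0.072 for lymphatic, -0.052 to 0.069 for mitochondrial and -0.048 to 0.053 for ribosomal genes. The cause of these changes was not tested. At this depth and n, limma recovered 58.1% of simulated 1.5-fold changes among 13680 genes.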

Other observations

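Tests chosen only after the result was seen are those of the heat shock and decay factor lists, the site-free zinc-finger genes, the coding sites, the UTR trend as an explanation, the library scores for seed sites, and those on immediate early genes and other splits of the libraries. The share of zinc-finger genes among the falls was also tested after it was noticed. No zinc-finger list was among the 30 gene lists, so every test of this family concerns a group of genes not set in advance. Of 18 tested heat shock chaperones, a list drawn up after its members were seen among the falls and given no set test, HSPA1A, HSPA1B and HSPA8 fell, 0 rose and 16 had a fold change below 0, with a median of -0.08 (-0.06 with median-of-ratios and -0.08 with quantile scaling). HSPA8, the abundant constitutive HSC70 gene, fell from 1466 ± 54.4 to 1122 ± 7.03 TPM (n = 3), and HSPA1A from 111 ± 6.39 to 73.3 ± 2.55 TPM, though reads may be shared between HSPA1A and HSPA1B. DNAJB1 had a log2 fold change of -0.37 (SE 0.06), while HSP90AB1 was at 0.01 (SE 0.06). Among 7 zinc-finger factors of mRNA decay, ZFP36 rose while its relative ZFP36L1 fell from 105 ± 4.81 to 81.5 ± 3.10 TPM. Other rises were AMOTL2 (0.50, SE 0.05), NEDD9 (0.53, SE 0.06), PIM1 (0.56, SE 0.07), TRIB1 (0.57, SE 0.07) and CSRNP1 (0.60, SE 0.10), of which NEDD9 and CSRNP1 overlap antisense genes and AMOTL2 a ribosomal pseudogene on its strand, so reads of these 3 are uncertain. SNORA10, a small nucleolar RNA, was listed at 0 in every control library and averaged 4.33 TPM in mimic libraries, an estimated 14 reads in total over an exon of RPS2 on the same strand, too few to show that it was absent from control cells.

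Other splits of the 6 libraries into 3 and 3 were counted once each. The real split called 59 genes, the highest of the other splits called 2, and 1 of 10 splits, the real split, called as many. At an unadjusted p under 0.05 the real split gave 1462 genes, while the split of control library 1 and mimic libraries 1 and 3 against the rest gave 1564, and the next gave 1061 and 900. It called 4 lists, the highest other split called 5, and 2 of 10 splits called as many. With 10 splits the share can never be under 0.05.

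Transcripts with miR-409-3p seed sites were not lower in mimic libraries, with a difference of 0.0046, although it was -0.0075, -0.0021 and -0.035 without control library 1, control library 2 and mimic library 2. Those differences were not adjusted for UTR length or GC. After that adjustment the rank-sum z of CAACATT was positive in the same fits, at 1.16, 1.11 and 2.29. A trend with UTR length or GC hiding a lowering is argued against, since after regression on both the difference was 0.0059 (95% interval 3.17e-05 to 0.013). For sites in the coding sequence instead, the difference was -0.0031 (-0.0098 to 0.0078) between 585 genes with a coding site only and 5010 with none. That interval covers the spread between genes only and was not adjusted for UTR length or GC. It was not repeated without single libraries, so coding sites stay open. Medians by coding site were -0.026 for an 8mer, -0.018 for a 7mer-m8, -0.017 for a 7mer-A1, -0.022 for a 6mer and -0.018 for none. For 1 mimic library without mimic, 2 libraries should score below every control. After adjustment for UTR length and GC 0 did, and before it 1 did (mimic library 3, at -0.064). Before adjustment mimic library 2, at 0.083, lay above every control. Adjusted scores were -0.0020 ± 0.0028 in control and 0.0033 ± 0.0057 in mimic libraries (two-sided exact permutation p = 0.3, smallest possible 0.1, n = 3). The prediction assumes a lowering of site transcripts in the libraries that received mimic. No such lowering was seen with all libraries, so this result cannot decide the point. Whether the mimic entered the microRNA machinery of these cells, or lowered protein without lowering RNA, was not measured in these libraries and stays open.

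Zinc-finger genes with ZNF, ZSCAN or ZKSCAN symbols were lower, with 332 of 436 fold changes below 0, 8 falls, 1 rise (ZNF267) and a median of -0.13 (-0.11 with median-of-ratios and -0.10 with quantile scaling). They made up 8 of 40 falling protein-coding genes against 3.61% of 12064 tested (two-sided Fisher's exact p = 7.58e-05, with genes taken as independent). This share was tested after it was noticed, so its p restates the observation that prompted it. A bias with GC, length or expression is argued against, as the median lay 0.10 below that of matched gene sets (difference -0.10, matched sets -0.041 to -0.011). So is 1 deviating library, as 3 of 3 mimic libraries scored below every control (two-sided exact permutation p = 0.1, the smallest possible). Seed sites as the whole cause are argued against by site-free zinc-finger genes, which lay at -0.12 relative to other site-free genes (95% interval -0.15 to -0.082), while a part played by sites stays open at a difference of -0.0079 (-0.056 to 0.044) between 158 genes with and 275 without a site. An effect of the mimic on this gene family and differences in handling between the groups were not tested and stay open.

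Immediate early genes were higher in mimic libraries, with library scores of -0.059 ± 0.043 in control and 0.069 ± 0.070 in mimic libraries (n = 3) and a two-sided exact permutation p of 0.1, the smallest possible. A single deviating mimic library is argued against by these scores, as all 3 mimic libraries lay above every control. Without each mimic library in turn the list median was at least 0.048 and the camera adjusted p at the preset correlation at most 8.05e-04. That p cannot decide the point, as splits that mixed the groups called up to 5 lists at the same correlation. With all libraries the list had a camera adjusted p of 0.871 with an estimated correlation. The fry adjusted p was 0.554. Estimated depths overlapped, at 32.2, 32.8 and 34.8 M reads in control and 32.1, 35.8 and 29.8 M in mimic libraries 1 to 3. The deepest and the shallowest mimic library, at scores of 0.0125 and 0.15, both lay above the highest control, at -0.018. Control library 1 and mimic library 1, nearly equal in depth, scored -0.10 and 0.047. A role of depth stays open, as the deepest mimic library exceeded the highest control by only 0.030, less than the control SD. Handling or harvest time cannot be told apart from the mimic for the difference of 0.13, as no label gives a date or order. A response to the mimic is a hypothesis that stays open beside them.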
